A study of Mus musculus with 8 samples.

How the data were processed

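Bulk RNA-seq profiles of mouse embryonic fibroblasts (MEFs) of the 4F2A strain were taken on days 2, 4, 6 and 8 of doxycycline, with 2 libraries per day and 8 libraries in all. Per the labels, total RNA was isolated with TRIzol and sequenced on a BGISEQ-500 instrument. The submitters' processing notes name Trimmomatic 0.39 for trimming, featureCounts without a version, and the genome build mm10. The aligner, the annotation release, the strandedness of the counting and the handling of reads that match several genes are not given in the sources used here.

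The deposited table holds 32108 genes and 8 columns of values in CPM, each gene's reads scaled by the authors to a library total of 1000000, although its name speaks of TPM. Within a library each value was a whole multiple of 1 hundredth of a constant step, the value of 1 read, which division by gene length would not leave. The step corresponds to 19409936 to 20161021 counted reads per library. Of the values above 0, 52.8% to 54.3% were whole reads (tolerance 0.02 hundredths of a read), so some reads were shared between genes. A floor of 3 reads, the upper limit that a count of 0 allows, equals 0.149 to 0.155 CPM, and it covers counting error only. Symbols and mm10 coordinates came from GENCODE M21 for 32029 gene identifiers, and 79 identifiers had no symbol. All columns belonged to a labelled library, and 0 columns belonged to no sample.

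The design was fixed before the data were examined, for values in TPM, and it was applied to the CPM values without other change. Genes with at least 1 CPM in at least 2 libraries were tested, 15358 in number. The model was fitted on log2(CPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with a coefficient for each day over all 8 libraries and 4 residual degrees of freedom. Each contrast (D4 against D2, D6 against D4, D8 against D6 and D8 against D2) was tested with limma's two-sided moderated test, and any difference between days with its moderated F test. P-values were adjusted by Benjamini-Hochberg over all tested genes, and a gene was called at an adjusted p under 0.05. Changes are differences of the means of log2(CPM + 1), which understate the fold of genes at low levels, and folds are ratios of mean CPM. Errors are SD over the 2 libraries of a day.

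With the design, 48 gene lists were fixed, covering the factors, pluripotency, lineage and cell type markers, the cell cycle, signalling, stress, metabolism and chromatin. A list was tested where at least 3 of its members passed the filter on low values. It was compared with all other tested genes by camera of limma with a preset correlation of 0.01 between genes, adjusted over the lists within a contrast, and again with an estimated correlation. The rotation test fry was run as an alternative. Counts of changed members are given over all tested genes and adjusted over the list alone. Calls of the first step (D4 against D2) and the last step (D8 against D6) were compared with Fisher's exact test, one-sided for an excess, for each pair of directions. These steps share no library, but both use the same fit and its estimate of each gene's spread, so their calls are not independent. Principal components and Euclidean distances used log2(CPM + 1) of the tested genes, centred per gene. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the table and drew the figures.

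The named genes followed a rule fixed with the design. It took, for each contrast, the 10 genes with the largest rise and the 10 with the largest fall among called genes with no overlap between the days' libraries and at least 5 CPM in the higher day, without unnamed gene models and pseudogenes. From each list it took up to 4 called members with the largest change. Pou5f1, Sox2, Klf4, Myc, Nanog, Cdh1, Thy1 and Col1a1 were always named, and members that stand apart within a list could be named. Genes outside the rule are marked where they appear, and some genes that the rule took are not printed.

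The fit was tested on simulated data with the noise of each gene and 100 changed genes of each size per comparison. Changes of 0.5 on the log2 scale were recovered for 77% (D4 against D2, 15059 genes run), 71% (D6 against D4, 15069 genes), 70% (D8 against D6, 15067 genes) and 80% (D8 against D2, 15057 genes) of the changed genes. Changes of 1 on the log2 scale were recovered for 90%, 91%, 89% and 94% in the same order. Of the unchanged genes, 19 of 14832, 17 of 14841, 18 of 14843 and 14 of 14830 were called. A list of 30 genes moved by 0.5 gave camera p-values between 2.3e-80 and 2.5e-56, and an unmoved list gave 0.39 to 0.94. The simulated noise was independent between genes, so this does not test camera on correlated lists. In the data the estimated correlation was 0.782 for ribosomal protein genes and 0.567 for genes of mitosis and G2/M. The data also held far more changed genes, with 62.5% called in D4 against D2.

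The alternatives were a pseudocount of 0.1, no filter on low values, a filter at 5 CPM, median-of-ratios scaling, quantile normalization, the replicate number as a block, a fit on the 2 days compared alone, an added 2-fold threshold, and leaving out each library in turn. Where a day keeps 1 library, that library is assumed to vary like the other days. A fit with limma's voom on the reads recovered from the step of each library was chosen after seeing the data. The labels call the 2 libraries of a day parallel replicates without saying whether they came from separate cultures or embryos. The numbers of the replicates showed little pairing of libraries across days. Over the 6 pairs of days the deviations of replicate 1 from its day's mean correlated, across genes, between -0.102 and 0.207. The highest value was that of D4 and D8, and an effect shared by libraries of the same number was not excluded. Alternative splicing, allele-specific expression and reads outside the table were not analysed here.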

Results

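Gene expression was followed in 4F2A MEFs, fibroblasts that carry a doxycycline-inducible cassette of the 4 reprogramming factors Oct4, Sox2, Klf4 and c-Myc (genes Pou5f1, Sox2, Klf4 and Myc), joined by self-cleaving peptides and placed in the Col1a1 locus. Per the labels the cells came from male embryos of 13.5 dpc and received 2 µg/mL doxycycline from day 0, in serum replacement medium with 1000 U/mL LIF that was renewed daily. The groups were D2, D4, D6 and D8, named by the day of harvest, with 2 libraries each. The titles call every sample a control, and the series holds no sample from day 0 and none without doxycycline, so all changes are between days of induction. The title of the series names the question, the difference between stages of reprogramming towards induced pluripotent stem cells. The labels do not say that the libraries of a day came from separate cultures or embryos, so the p-values measure the spread between these samples, which may be technical.

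The libraries held 20.16 and 20.08 (D2), 20.03 and 19.95 (D4), 19.51 and 19.55 (D6), and 19.41 and 19.51 (D8) times 1000000 counted reads, with 20784 to 22080 genes above 0. The 10 highest genes took 7.77% to 9.24% of the reads. Fn1, the gene of fibronectin, was the highest gene in the D2 libraries, Col1a1, a chain of type I collagen, in the D4 libraries, and mt-Co1, a mitochondrial subunit of cytochrome c oxidase, in the D6 and D8 libraries. Of 15358 tested genes, 12342 (80.4%) differed between days in limma's F test. The first principal component held 81.9% of the variance and the second 12.3%. The distance between single libraries of 2 days was on average 83.6 from D2 to D4, 46.7 from D4 to D6 and 28.1 from D6 to D8. Between the replicates of a day it was 16.4 to 19.6. Replicates differed by more than counting error, with a mean chi-square per gene of 1.38 for D2, 5.6 for D4, 3.75 for D6 and 4.23 for D8, where counting error alone gives about 1.

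**Figure D1:**
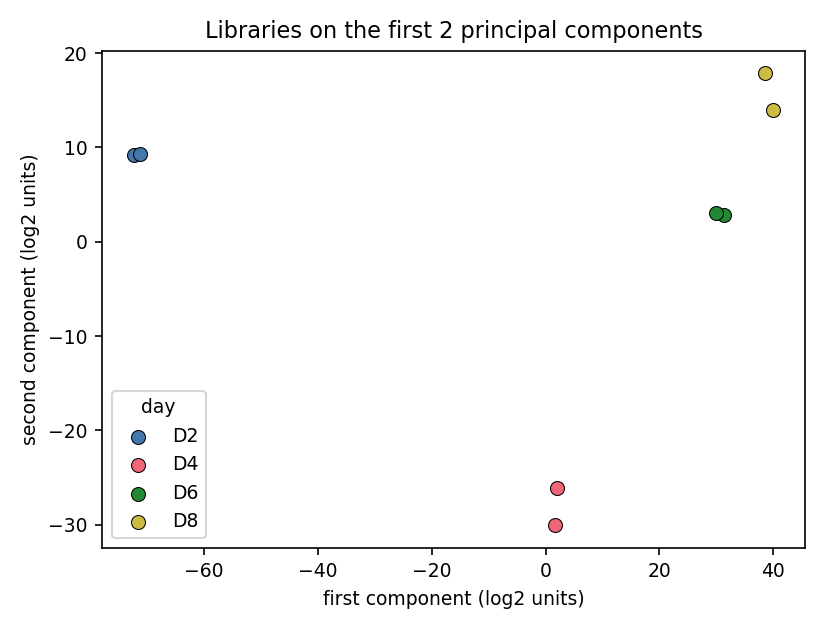
Principal components of log2(CPM + 1) over the 15358 tested genes, with the first component (81.9% of the variance) on the x axis and the second (12.3%) on the y axis, both in log2 units, and a point per library coloured by day. The D2 libraries lie at -72.19 and -71.27 on the first component and the D8 libraries at 38.6 and 39.91.

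The 4 factor genes were well above the floor on every day and rose until D6. Pou5f1 (chromosome 17, 35506018 to 35510772) stood at 113 ± 2 CPM in D2 and 281 ± 6.52 CPM in D8, and Sox2 at 109 ± 2.57 and 208 ± 5.98 CPM (SD, n = 2). Klf4 stood at 329.8 ± 5.29 and 593 ± 4.35 CPM, and Myc at 394 ± 14.5 and 717 ± 6.52 CPM. The table gives a single value per gene, so reads of the cassette and of the cells' own copies were not separated. Nanog, a transcription factor of the pluripotent state, stayed between 0.252 and 0.569 CPM in every library, below the filter, and was not tested.

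**Figure D2:**
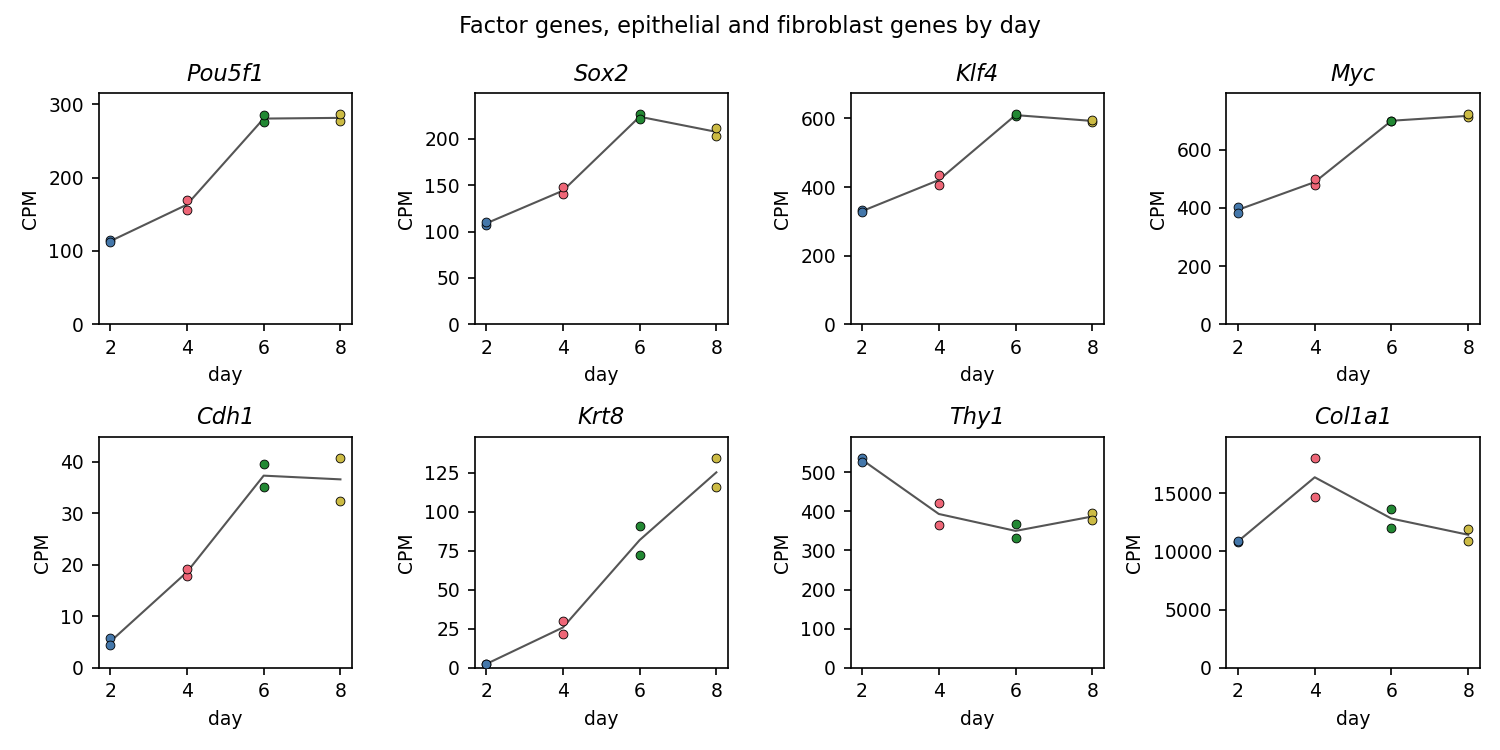
CPM (y axis, from 0) by day (x axis) for the 4 factor genes, the epithelial genes Cdh1 and Krt8 and the fibroblast genes Thy1 and Col1a1, with a point per library and a line through the day means. Pou5f1 went from 113 CPM in D2 to 280.4 CPM in D6 and 281 CPM in D8, and Krt8 from 2.4 to 125 CPM between D2 and D8.

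Sex-linked genes, apart from Xist chosen after their values were seen, did not follow the label of male embryos. Xist, the RNA that coats the inactive X chromosome (chromosome X, 103460366 to 103483254), lay between 702 and 1240 CPM in the 8 libraries. The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty reached at most 0.333, 0.11, 0.309 and 0.0964 CPM, and together they made 0.0239% to 0.0611% of the reads of their X-linked copies Ddx3x, Kdm5c, Eif2s3x and Kdm6a. Of the 281 Y-chromosome genes listed, 2 reached 1 CPM in any library, Gapdh-ps15 at 19.5 to 53.2 CPM and Gm47283 at 38.4 to 64.6 CPM. Xist rose from 722 ± 28.3 CPM in D2 to 1220 ± 18.9 CPM in D8 (0.76 on the log2 scale, adjusted p = 1.9e-08).

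The first step, D4 against D2, asked what changed between the early days of induction, and it was the largest of the 3 steps by number of called genes. Interferon response genes and the angiotensin receptor gene Agtr2 rose steeply, and most genes of contraction, glycolysis and hypoxia fell. Agtr2 (chromosome X, 21484544 to 21489164) rose 195-fold, from 0.87 ± 0.103 to 169 ± 15.6 CPM (SD, n = 2). Atf3, a stress-induced repressor (chromosome 1, 191170296 to 191218039), fell from 91.6 ± 10.7 to 1.33 ± 0.11 CPM, 0.0145 times its D2 level. Lum, which encodes the matrix proteoglycan lumican (chromosome 10, 97565128 to 97572703), rose 40.1-fold to 453 ± 37 CPM.

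Of 31 tested interferon response genes, 30 rose and 0 fell (the same adjusted over the list alone), with camera adjusted p = 1.1e-12, and adjusted p = 0.32 with an estimated correlation. Their median change was 3.18 on the log2 scale. Ifit3 (chromosome 19, 34583531 to 34588731) rose 72-fold from 1.5 ± 0.365 to 108 ± 7.26 CPM, Ifit1 51.2-fold to 155 ± 14.3 CPM, and Ifit3b, a near-identical copy of Ifit3, 66.1-fold to 74.7 ± 5.54 CPM. The products of this family block viral translation. Oasl2, a relative of the antiviral oligoadenylate synthetases, rose from 1.27 ± 0.161 to 94.1 ± 26.6 CPM, and Mx1, an antiviral GTPase, from 0.397 ± 0.491 to 35.9 ± 4.65 CPM. Among macrophage and haematopoietic genes, 4 of 21 tested rose and 1 fell (2 and 1 adjusted over the list alone), with camera adjusted p = 1. Mrc1, the macrophage mannose receptor, rose from 2.53 ± 0.414 to 9.86 ± 0.736 CPM, while Lyz2, lysozyme of macrophages and the most abundant member, stood at 43.2 ± 11.6 and 50.7 ± 2.44 CPM (adjusted p = 0.11).

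Secreted enzymes and chemokines moved in both directions. Secreted inflammatory and senescence-associated genes counted 14 higher and 8 lower of 26 tested (the same adjusted over the list alone), with camera adjusted p = 0.45. Mmp3, the matrix protease stromelysin, rose 41.4-fold from 9.98 ± 3.07 to 414 ± 46 CPM, and the neutrophil chemokines Cxcl5 and Cxcl1 rose by 4.16 and 3.86 on the log2 scale. Steap4, a metalloreductase, rose from 2.76 ± 0.605 to 99.5 ± 15.1 CPM. Of 39 tested fibroblast and mesenchymal genes, 25 rose and 9 fell (the same adjusted over the list alone), with camera adjusted p = 0.019, and adjusted p = 0.47 with an estimated correlation. Besides Lum, the growth factor receptor gene Pdgfra rose to 65.2 ± 2.86 CPM from 11 ± 0.84, the collagen gene Col3a1 to 10530 ± 19.7 from 2047 ± 23.1, and the surface protease gene Fap to 31.2 ± 0.0505 from 5.49 ± 0.935 CPM. Col1a1 rose from 10870 ± 26.5 to 16370 ± 2340 CPM, and Thy1, a surface marker of fibroblasts, fell from 532 ± 6.46 to 393 ± 40.1 CPM.

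Contractile genes fell together. Among smooth muscle and contractile genes, 1 of 21 tested rose and 20 fell (the same adjusted over the list alone), with camera adjusted p = 2.2e-15, and adjusted p = 0.28 with an estimated correlation. Their median change was -1.6. Cnn1, calponin of smooth muscle (chromosome 9, 22099216 to 22109630), fell from 140.3 ± 2.58 to 8.48 ± 0.626 CPM. Lmod1, an actin nucleator, fell from 35.7 ± 1.05 to 2.9 ± 0.15 CPM, and Acta2, smooth muscle actin, from 2394 ± 76.2 to 512 ± 7.17 CPM. Ankrd1, an ankyrin repeat protein of muscle, fell from 17.9 ± 1.6 to 0.951 ± 0.139 CPM. TGF-beta pathway genes counted 6 higher and 11 lower of 22 tested (the same adjusted over the list alone), with camera adjusted p = 0.019, and adjusted p = 0.53 with an estimated correlation. Ccn2, a matricellular protein, fell from 684 ± 38.1 to 103 ± 13 CPM, and Thbs1, thrombospondin, from 10420 ± 63.5 to 2590 ± 35.8 CPM. The coreceptor gene Tgfbr3 rose from 24.6 ± 0.669 to 99.5 ± 3.61 CPM. Quantile normalization gave this list an adjusted p of 0.22, and leaving out D4 replicate 1 gave 0.067. Gjb2, a gap junction protein, fell from 34.4 ± 2.64 to 0.40 ± 0.14 CPM, and Nipal1, a magnesium transporter, from 46.3 ± 0.182 to 1.53 ± 0.243 CPM.

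The AP-1 and immediate-early list split. As fixed, it also holds Runx1, Runx2, Tead3, Tead4, Cebpa and Cebpb, which are not AP-1 subunits, and its counts in every contrast include them. Of 28 tested AP-1 and immediate-early genes, 7 rose and 18 fell (the same adjusted over the list alone), with camera adjusted p = 6.1e-04, and adjusted p = 0.32 with an estimated correlation. Besides Atf3, Egr3, an early growth response factor, fell from 51.6 ± 2.24 to 4.6 ± 0.155 CPM. Fos, the AP-1 subunit (chromosome 12, 85473890 to 85477273), rose 44.2-fold from 2.93 ± 0.711 to 129.8 ± 1.54 CPM, and Egr1, a zinc finger factor induced by growth signals, rose from 49.5 ± 6.81 to 396 ± 3.08 CPM. Noct, which encodes nocturnin, fell from 125 ± 7.32 to 12.3 ± 1.93 CPM.

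Glucose metabolism genes fell. Among glycolysis genes, 3 of 22 tested rose and 18 fell (the same adjusted over the list alone), with camera adjusted p = 1.5e-10, and adjusted p = 0.32 with an estimated correlation. Hypoxia genes counted 1 higher and 18 lower of 21 tested (the same adjusted over the list alone), with camera adjusted p = 4.9e-11, and adjusted p = 0.28 with an estimated correlation. Slc16a3, the lactate exporter, fell from 106 ± 2.87 to 7.38 ± 0.651 CPM, Slc2a1, a glucose transporter, from 134 ± 2.51 to 14.4 ± 0.153 CPM. Ldha, lactate dehydrogenase, fell from 955 ± 15 to 270.2 ± 21.8 CPM, and Bnip3, a mitophagy receptor induced by low oxygen, from 59.5 ± 0.23 to 7.44 ± 1.61 CPM. Of 15 tested heat shock genes, 0 rose and 14 fell (0 and 15 adjusted over the list alone), with camera adjusted p = 8.6e-08, and adjusted p = 0.28 with an estimated correlation. The small chaperone genes Hspb1 and Cryab fell from 95.7 ± 5.17 to 27.6 ± 2.7 CPM and from 289 ± 0.875 to 112 ± 0.511 CPM. Among genes of the unfolded protein response, 1 of 20 tested rose and 16 fell (the same adjusted over the list alone), with camera adjusted p = 7.9e-07, and adjusted p = 0.28 with an estimated correlation. Trib3, a pseudokinase induced by stress, fell by 1.39 on the log2 scale, and Ddit3, a stress transcription factor, fell by 1.33. Genes of ribosome biogenesis and MYC targets counted 2 higher and 20 lower of 30 tested (3 and 21 adjusted over the list alone), with camera adjusted p = 2.7e-05, and adjusted p = 0.28 with an estimated correlation. Odc1, the enzyme of polyamine synthesis, fell from 109.5 ± 2.25 to 77.6 ± 0.678 CPM. The glycolysis and hypoxia lists share members such as Slc2a1 and Ldha, and Ldha is also in the list of ribosome biogenesis and MYC targets. The results of these lists are therefore not independent. Sterol enzymes rose. Of 24 tested genes of cholesterol synthesis, 19 rose and 2 fell (the same adjusted over the list alone), with camera adjusted p = 0.0013, and adjusted p = 0.43 with an estimated correlation. Dhcr7, the last reductase of the pathway, rose from 22.3 ± 1.02 to 44.8 ± 2.14 CPM.

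Cell cycle genes rose in this step. Among genes of DNA replication and S phase, 31 of 33 tested rose and 0 fell (the same adjusted over the list alone), with camera adjusted p = 8.7e-05, and adjusted p = 0.47 with an estimated correlation. Genes of mitosis and G2/M counted 28 higher and 0 lower of 32 tested (30 and 0 adjusted over the list alone), with camera adjusted p = 5.6e-04, and adjusted p = 0.56 with an estimated correlation. Cdc45, a part of the replicative helicase, rose from 5.93 ± 0.51 to 12.4 ± 0.761 CPM, and Kif11, the mitotic kinesin, from 25.4 ± 1.96 to 47.6 ± 6 CPM. Of 16 tested enzymes of DNA methylation and demethylation, 13 rose and 0 fell (the same adjusted over the list alone), with camera adjusted p = 0.0053, and adjusted p = 0.32 with an estimated correlation. Tet1, a dioxygenase of methylcytosine, rose from 1.69 ± 0.427 to 8.61 ± 1.23 CPM, and the de novo methyltransferase gene Dnmt3a from 43.8 ± 0.287 to 107 ± 3.77 CPM. Among Polycomb and histone modifier genes, 25 of 34 tested rose and 3 fell (26 and 3 adjusted over the list alone), with camera adjusted p = 0.0086, and adjusted p = 0.44 with an estimated correlation. Cbx6, a Polycomb subunit, rose by 1.12 on the log2 scale.

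The factor genes rose in this step, Pou5f1 by 0.52, Sox2 by 0.4, Klf4 by 0.35 and Myc by 0.31 on the log2 scale (adjusted p = 0.053 for the list). Only 16 of 40 fixed genes of the pluripotency network passed the filter. Genes of the pluripotency network counted 9 higher and 2 lower of 16 tested (the same adjusted over the list alone), with camera adjusted p = 0.24. L1td1, an RNA-binding protein of pluripotent cells, rose from 8.93 ± 0.219 to 45.5 ± 2.35 CPM, and Klf5, a Krüppel-like factor, fell from 8.08 ± 0.305 to 0.926 ± 0.463 CPM. Of 8 tested early and intermediate reprogramming markers, 7 rose and 1 fell (the same adjusted over the list alone), with camera adjusted p = 0.12. Cdh1, E-cadherin of epithelial junctions, rose from 5.07 ± 0.899 to 18.6 ± 0.973 CPM, and Cd44, a hyaluronan receptor, fell from 892 ± 3.66 to 485 ± 24.1 CPM. Among epithelial genes, 14 of 24 tested rose and 5 fell (16 and 5 adjusted over the list alone), with camera adjusted p = 0.36. The keratin gene Krt8 rose from 2.4 ± 0.336 to 25.8 ± 6.26 CPM, and the keratin gene Krt19 fell from 31.1 ± 0.367 to 5.53 ± 1.15 CPM. Genes of stratified epithelium counted 8 higher and 3 lower of 20 tested (the same adjusted over the list alone), with camera adjusted p = 0.52. The galectin gene Lgals7 rose from 1.67 ± 0.04 to 15.9 ± 4.13 CPM.

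In total 6276 genes were higher and 3330 lower in D4 than in D2 (limma, adjusted p under 0.05), and 981 and 528 of these changed at least 2-fold. The median of all tested genes shifted by 0.107 on the log2 scale, and the split between directions depended on the scaling. Of called genes, 65.3% were higher on the deposited scale, 52% after median-of-ratios scaling and 47.1% after quantile normalization.

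**Figure D3:**
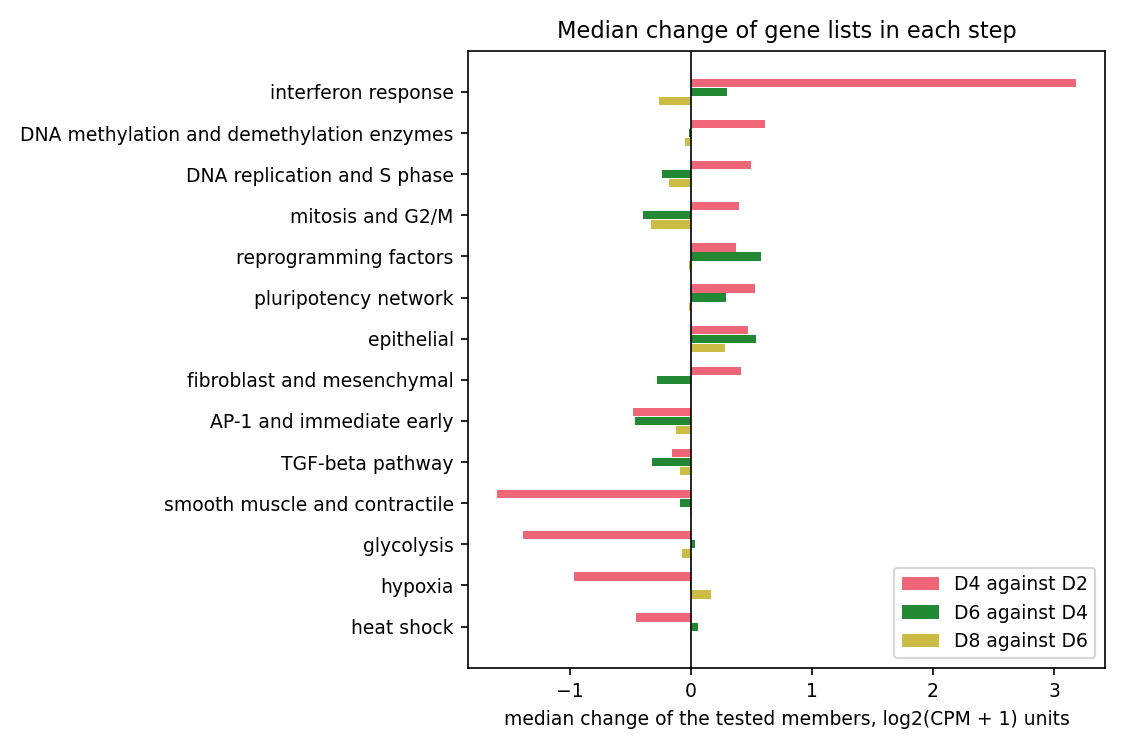
Median change on the log2(CPM + 1) scale (x axis) of the tested members of 14 gene lists (y axis), with a bar per step of the time course. The interferon list has a median of 3.18 in D4 against D2 and 0.3 in D6 against D4, and the smooth muscle list -1.6 in D4 against D2.

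The second step, D6 against D4, asked what changed in the middle of the time course. Immediate-early genes such as Fosb, Fos and Egr1 fell back, most fibroblast and mesenchymal genes and most TGF-beta genes fell, and the 4 factor genes and 14 of 24 epithelial genes rose. Fosb (chromosome 7, 19302696 to 19310051) fell from 114 ± 13.2 to 2.02 ± 0.329 CPM (SD, n = 2). Fos fell from 129.8 ± 1.54 to 4.97 ± 0.00688 CPM and Egr1 (chromosome 18, 34859823 to 34864984) from 396 ± 3.08 to 43.5 ± 2.7 CPM. Lbp, the binding protein of bacterial lipopolysaccharide (chromosome 2, 158306493 to 158332852), rose 7.89-fold from 24 ± 1.45 to 189 ± 12.2 CPM. Piwil2, an Argonaute protein of the piRNA pathway (chromosome 14, 70372477 to 70429383), rose 7.84-fold from 3.55 ± 0.293 to 27.9 ± 1.99 CPM.

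Of 28 tested AP-1 and immediate-early genes, 1 rose and 20 fell (1 and 21 adjusted over the list alone), with camera adjusted p = 1.3e-14, and adjusted p = 0.21 with an estimated correlation. Zfp36, which destabilizes AU-rich mRNAs, fell from 83.5 ± 1.09 to 20.2 ± 2.09 CPM, and Dusp1, a MAP kinase phosphatase, from 81.6 ± 0.262 to 25.5 ± 0.562 CPM, against D2 levels of 20.2 ± 0.486 and 37.7 ± 2.09 CPM. Among TGF-beta pathway genes, 1 of 22 tested rose and 18 fell (1 and 20 adjusted over the list alone), with camera adjusted p = 2.3e-13, and adjusted p = 0.21 with an estimated correlation. Ccn1, a matricellular protein (chromosome 3, 145646976 to 145649981), fell from 293 ± 12.1 to 76.9 ± 0.903 CPM, Thbs1 from 2590 ± 35.8 to 1255 ± 131 CPM, and the ligand gene Tgfb3 from 238 ± 17.6 to 129 ± 0.383 CPM. Fibroblast and mesenchymal genes counted 6 higher and 23 lower of 39 tested (6 and 25 adjusted over the list alone), with camera adjusted p = 2.5e-08, and adjusted p = 0.21 with an estimated correlation. The collagen genes Col5a1 and Col6a3 fell from 3979 ± 164 to 2302 ± 224 CPM and from 1400 ± 25.9 to 809.6 ± 101 CPM. Dcn, the proteoglycan decorin, rose from 633 ± 19.3 to 1114 ± 86.4 CPM. Col1a1 fell from 16370 ± 2340 to 12820 ± 1160 CPM, and Thy1 stood at 350 ± 26 CPM (adjusted p = 0.073). The call of Col1a1 ended without D4 replicate 2 (adjusted p = 0.18), D6 replicate 1 (0.19) or either D2 replicate (0.063), without a filter on low values (0.23) and in a fit of only the 2 days compared (0.081). Spp1, the bone matrix protein osteopontin, fell from 449.6 ± 106 to 108 ± 31 CPM, Cthrc1, a secreted protein of matrix remodelling, from 122 ± 15.1 to 37.3 ± 5.38 CPM. Fbn2, a fibrillin, fell from 461 ± 55.9 to 174 ± 13.7 CPM, and Adgrg1, an adhesion receptor, from 14.1 ± 1.38 to 4.3 ± 0.658 CPM. Of 26 tested secreted inflammatory and senescence-associated genes, 1 rose and 16 fell (2 and 17 adjusted over the list alone), with camera adjusted p = 8.3e-09, and adjusted p = 0.21 with an estimated correlation. The growth factor gene Ereg fell by 0.97 on the log2 scale, and the chemokine gene Ccl7 fell by 0.94. Among smooth muscle and contractile genes, 1 of 21 tested rose and 9 fell (2 and 9 adjusted over the list alone), with camera adjusted p = 5.4e-04, and adjusted p = 0.41 with an estimated correlation. Vcl, vinculin of focal adhesions, fell from 227 ± 11.1 to 126 ± 9.91 CPM. BMP and ID genes counted 2 higher and 6 lower of 21 tested (the same adjusted over the list alone), with camera adjusted p = 0.0048, and adjusted p = 0.21 with an estimated correlation. The ligand gene Bmp4 fell by 0.73 on the log2 scale, and the inhibitor gene Id4 rose by 0.83.

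**Figure D4:**
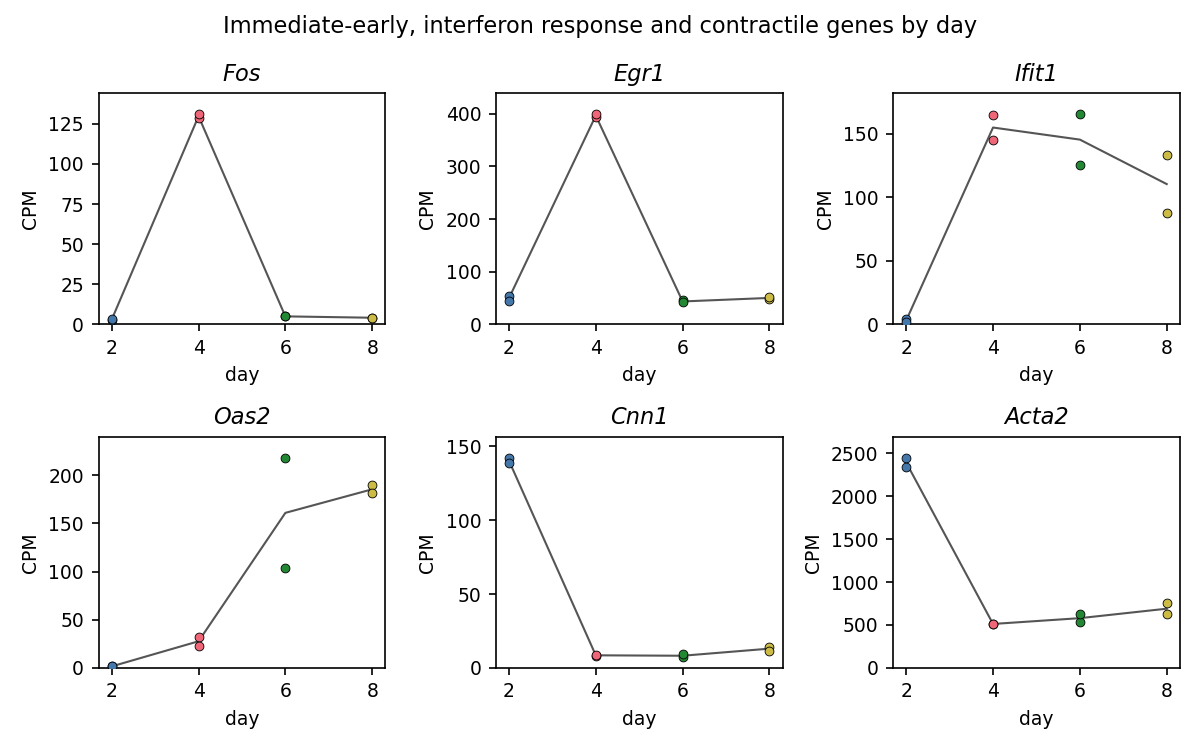
CPM (y axis, from 0) by day (x axis) for Fos, Egr1, Ifit1, Oas2, Cnn1 and Acta2, with a point per library and a line through the day means. Fos stood at 129.8 CPM in D4 against 2.93 CPM in D2 and 4.97 CPM in D6, and Cnn1 fell from 140.3 CPM in D2 to 8.48 CPM in D4.

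The factor genes rose again, Pou5f1 by 0.78 and Sox2 by 0.63 on the log2 scale (camera adjusted p = 2.5e-04, and adjusted p = 0.41 with an estimated correlation). Klf4 reached 609.6 ± 2.55 and Myc 700 ± 0.969 CPM. Of 24 tested epithelial genes, 14 rose and 1 fell (15 and 1 adjusted over the list alone), with camera adjusted p = 5.2e-04, and adjusted p = 0.21 with an estimated correlation. Among genes of stratified epithelium, 10 of 20 tested rose and 0 fell (11 and 0 adjusted over the list alone), with camera adjusted p = 0.0048, and adjusted p = 0.28 with an estimated correlation. Dsg2, a desmosomal cadherin (chromosome 18, 20558074 to 20604521), rose from 1.63 ± 0.208 to 11.2 ± 0.612 CPM, Krt8 from 25.8 ± 6.26 to 81.8 ± 13.2 CPM. Cdh1 rose from 18.6 ± 0.973 to 37.3 ± 3.21 CPM, and Elf3, an epithelial transcription factor, from 1.28 ± 0.357 to 9.39 ± 1.25 CPM. Lgals7 rose from 15.9 ± 4.13 to 73.1 ± 7.1 CPM, and Col17a1, a collagen of hemidesmosomes, from 1.13 ± 0.174 to 10.6 ± 1.14 CPM. Genes of the pluripotency network counted 8 higher and 2 lower of 16 tested (the same adjusted over the list alone), with camera adjusted p = 0.08. Gdf3, a TGF-beta family ligand, rose from 1.25 ± 0.354 to 4.92 ± 1.31 CPM, and Tfcp2l1, a transcription factor of naive pluripotency, from 0.851 ± 0.285 to 3.41 ± 0.584 CPM. Klf2, a Krüppel-like factor, fell from 9.68 ± 1.27 to 3.69 ± 0.44 CPM.

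Of 32 tested genes of mitosis and G2/M, 0 rose and 27 fell (0 and 30 adjusted over the list alone), with camera adjusted p = 1.6e-14, and adjusted p = 0.41 with an estimated correlation. Among genes of DNA replication and S phase, 0 of 33 tested rose and 16 fell (0 and 17 adjusted over the list alone), with camera adjusted p = 4.7e-08, and adjusted p = 0.43 with an estimated correlation. Tacc3, a spindle protein, fell from 50.9 ± 2.37 to 30.4 ± 1.19 CPM, and Rrm2, the ribonucleotide reductase subunit, from 108 ± 4.4 to 70.4 ± 3.93 CPM. Ribosomal protein genes counted 26 higher and 0 lower of 36 tested (27 and 0 adjusted over the list alone), with camera adjusted p = 2.4e-05, and adjusted p = 0.68 with an estimated correlation. Rplp0, a stalk protein, rose from 961 ± 101 to 1304 ± 46.1 CPM. In the first step 0 rose and 11 fell of 36 (0 and 6 adjusted over the list alone), with camera adjusted p = 1.6e-04, and adjusted p = 0.62 with an estimated correlation. Quantile normalization turned the median of the ribosomal protein genes in that step from -0.14 to 0.02 (adjusted p = 0.69).

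Of 31 tested interferon response genes, 12 rose and 0 fell (13 and 0 adjusted over the list alone), with camera adjusted p = 0.13. Oas2, an oligoadenylate synthetase, rose from 27.6 ± 6.61 to 161 ± 80.6 CPM, with 103.9 CPM in D6 replicate 1 and 217.9 CPM in D6 replicate 2. Myoc, which encodes myocilin (chromosome 1, 162639155 to 162649693), rose from 42.9 ± 2.34 to 257 ± 5.17 CPM, and Myocos, which overlaps it on the other strand (chromosome 1, 162647193 to 162658219), from 3.19 ± 0.00856 to 18.7 ± 0.499 CPM. Grm4, a glutamate receptor, rose from 2.95 ± 0.433 to 21.7 ± 4.21 CPM, and Kcne1l, a potassium channel subunit, from 1.15 ± 0.209 to 9.42 ± 2.11 CPM.

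In total 3864 genes were higher and 1928 lower in D6 than in D4 (limma), and 300 and 37 of these changed at least 2-fold. Of the called genes 66.7% were higher, against 48.7% after median-of-ratios scaling and 47.7% after quantile normalization, which called 2942 genes lower.

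The third step, D8 against D6, asked what still changed late in the time course, and it was the smallest. Of the epithelial genes 7 of 24 rose, while 19 of 32 mitosis genes, 7 of 31 interferon genes and the chaperone genes Hspa1a and Hspa1b fell. Cyp4a10, a fatty acid hydroxylase (chromosome 4, 115518264 to 115533649), rose 7.66-fold from 1.09 ± 0.183 to 8.37 ± 0.781 CPM (SD, n = 2). Col17a1 (chromosome 19, 47646344 to 47692094) rose 3.49-fold from 10.6 ± 1.14 to 36.9 ± 1.62 CPM. Hspa1a (chromosome 17, 34969190 to 34972156) and Hspa1b, near-identical genes of the inducible chaperone of heat shock, fell from 17.9 ± 4.83 to 5.83 ± 0.461 CPM and from 20.4 ± 5.31 to 7.8 ± 0.899 CPM.

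Among epithelial genes, 7 of 24 tested rose and 0 fell (9 and 0 adjusted over the list alone), with camera adjusted p = 0.0018, and adjusted p = 0.67 with an estimated correlation. With a filter at 5 CPM the adjusted p was 0.2 and the median change -0.04. Dsg2 rose from 11.2 ± 0.612 to 23.1 ± 0.355 CPM, and Krt8 from 81.8 ± 13.2 to 125 ± 13 CPM. The call of Krt8 ended without D6 replicate 1 (adjusted p = 0.16), D8 replicate 1 (adjusted p = 0.15) or D8 replicate 2 (adjusted p = 0.051), and without a filter on low values (0.17). Genes of stratified epithelium counted 3 higher and 0 lower of 20 tested (4 and 0 adjusted over the list alone), with camera adjusted p = 0.043, and adjusted p = 0.67 with an estimated correlation. That call ended in several settings, with adjusted p from 0.05 with a replicate block to 0.25 without D8 replicate 1, and it ended also without D6 replicate 1 (0.16) or D8 replicate 2 (0.061). Lgals7, of this list, rose from 73.1 ± 7.1 to 123 ± 9.52 CPM, with adjusted p = 0.051 without D6 replicate 1 and 0.06 without D8 replicate 1, and its call also ended without a filter on low values. The kallikrein protease gene Klk1 rose from 3.33 ± 0.547 to 11.8 ± 2.05 CPM, and its relative Klk11 rose by 1.34 on the log2 scale. Aoc1, the enzyme that degrades histamine, rose from 1.69 ± 0.00234 to 8.33 ± 0.248 CPM, Tspan1, a tetraspanin, from 2.28 ± 0.401 to 7.02 ± 1.01 CPM, and Fgfbp1, a carrier of fibroblast growth factors, from 4.87 ± 0.441 to 12.8 ± 2.08 CPM. March1, a ubiquitin ligase of membranes, rose from 10.2 ± 1.75 to 25.8 ± 3.8 CPM, Spaar, a small polypeptide, from 3.06 ± 0.0892 to 8.41 ± 0.318 CPM, and Sox1, a transcription factor of neural precursors, from 1.95 ± 0.654 to 6.41 ± 2.72 CPM.

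The 4 factor genes did not pass the test in this step, with changes between -0.11 (Sox2, adjusted p = 0.18) and 0.03 (Myc, adjusted p = 0.7). Of 16 tested genes of the pluripotency network, 2 rose and 1 fell (4 and 2 adjusted over the list alone), with camera adjusted p = 0.58. Their median change was -0.02 and their mean change 0.07. Tfcp2l1 rose from 3.41 ± 0.584 to 8.02 ± 0.306 CPM. Cdh1 stood at 36.5 ± 5.87 CPM (adjusted p = 0.89). Among fibroblast and mesenchymal genes, 6 of 39 tested rose and 2 fell (7 and 3 adjusted over the list alone), with camera adjusted p = 0.52. Their median change was -0.01 and their mean change 0.05. Lum, Dcn and Postn, a matricellular protein, rose by 0.65, 0.68 and 0.61 on the log2 scale. Col1a1 and Thy1 did not pass the test, at 11430 ± 705 and 387 ± 12.7 CPM.

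Genes of mitosis and G2/M counted 0 higher and 19 lower of 32 tested (0 and 26 adjusted over the list alone), with camera adjusted p = 5.4e-15, and adjusted p = 0.67 with an estimated correlation. Of 33 tested genes of DNA replication and S phase, 0 rose and 11 fell (0 and 14 adjusted over the list alone), with camera adjusted p = 5.6e-08, and adjusted p = 0.67 with an estimated correlation. Plk1, the mitotic polo-like kinase, fell from 29.5 ± 4.74 to 18.6 ± 1.92 CPM (adjusted p = 0.053 without D8 replicate 1 and 0.081 without a filter on low values). Rrm2 fell from 70.4 ± 3.93 to 48.3 ± 5.94 CPM, and E2f8, a repressor of cell cycle genes, from 10.2 ± 0.275 to 5.7 ± 0.261 CPM. Among interferon response genes, 1 of 31 tested rose and 7 fell (2 and 9 adjusted over the list alone), with camera adjusted p = 0.0064, and adjusted p = 0.76 with an estimated correlation. Without D6 replicate 2 the median of this list turned from -0.26 to 0.07 (adjusted p = 0.79), and without D8 replicate 1 its adjusted p was 0.098. Mx1 fell from 44.6 ± 9.48 to 19.9 ± 9.8 CPM, and Rsad2, the antiviral enzyme viperin, from 55.6 ± 4.78 to 26 ± 13.1 CPM. Ifit2 fell from 47.9 ± 9.59 to 27.8 ± 14.9 CPM, and Cmpk2, a nucleotide kinase next to Rsad2, from 37.2 ± 3.49 to 21.5 ± 8.83 CPM. Without D8 replicate 1 the adjusted p of Mx1, Rsad2, Ifit2 and Cmpk2 was 0.16, 0.2, 0.28 and 0.22, and without D6 replicate 1 it was 0.14, 0.14, 0.26 and 0.17. With a pseudocount of 0.1 it was 0.2, 0.13, 0.063 and 0.075, and without a filter on low values 0.18, 0.2, 0.26 and 0.2. Rsad2, Ifit2 and Cmpk2 also missed the threshold without D6 replicate 2, with Ifit2 at 0.08. In total the call of Ifit2 ended in 10 of 16 settings, also without D2 replicate 1 (0.066) or 2 (0.067), with median-of-ratios scaling (0.054), quantile normalization (0.06) and only the 2 days compared (0.058). Macrophage and haematopoietic genes counted 0 higher and 2 lower of 21 tested (0 and 8 adjusted over the list alone), with camera adjusted p = 0.0018, and adjusted p = 0.74 with an estimated correlation. Without D6 replicate 2 the adjusted p of the macrophage list was 0.077. Among SWI/SNF and chromatin remodeler genes, 0 of 27 tested rose and 3 fell (the same adjusted over the list alone). Camera gave an adjusted p of 0.0039, and 0.67 with an estimated correlation. Enzymes of DNA methylation and demethylation counted 0 higher and 3 lower of 16 tested (0 and 4 adjusted over the list alone). Their camera adjusted p was 0.03, and 0.67 with an estimated correlation. Of 21 tested hypoxia genes, 4 rose and 1 fell (6 and 1 adjusted over the list alone), with camera adjusted p = 0.0059, and adjusted p = 0.74 with an estimated correlation. Without D6 replicate 1 the adjusted p of the hypoxia list was 0.2. Pde2a, a phosphodiesterase of cyclic nucleotides, fell from 11.7 ± 0.921 to 4.87 ± 0.217 CPM, Lama1, a laminin chain, from 15 ± 0.347 to 8.76 ± 0.368 CPM, and Dusp15, a phosphatase, from 5.17 ± 0.442 to 2.83 ± 0.446 CPM. The adjusted p of Dusp15 was 0.056 without D6 replicate 1, 0.061 without D8 replicate 2 and 0.076 without a filter on low values.

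In total 725 genes were higher and 674 lower in D8 than in D6 (limma), and 40 and 6 of these changed at least 2-fold. Without a filter on low values 210 and 134 genes were called. Leaving out a library gave between 212 (without D8 replicate 1) and 907 (without D4 replicate 2) higher genes and between 186 (without D8 replicate 1) and 836 (without either D4 replicate) lower genes.

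The whole span, D8 against D2, asked how far the cells had moved by the last day sampled. Myoc, Lbp, Agtr2 and Lum rose steeply, 30 of 31 interferon response genes were higher, and 19 of 21 smooth muscle and contractile genes were lower. Myoc rose 298-fold from 1.21 ± 0.0141 to 359.5 ± 2.45 CPM (SD, n = 2). Lbp rose 188-fold to 313 ± 4.32 CPM, Agtr2 240-fold to 208 ± 25.2 CPM and Lum 74.6-fold to 844 ± 35.2 CPM. Atp2a3, a calcium pump of the endoplasmic reticulum (chromosome 11, 72961169 to 72993044), rose 80.1-fold from 7.19 ± 0.00334 to 576 ± 56.9 CPM. Saa3, an acute-phase apolipoprotein (chromosome 7, 46711998 to 46715700), rose from 0.178 ± 0.178 to 125 ± 19.3 CPM. Fmo1, a flavin monooxygenase (chromosome 1, 162829561 to 162866610), rose from 0.242 ± 0.176 to 93.8 ± 1.6 CPM, and Kera, the proteoglycan keratocan (chromosome 10, 97606879 to 97613692), from 0.0498 ± 0.0704 to 61.5 ± 1.02 CPM. The changes of Saa3, Fmo1 and Kera were 6.74, 6.26 and 5.9 on the log2 scale.

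Among interferon response genes, 30 of 31 tested rose and 0 fell (the same adjusted over the list alone), with camera adjusted p = 1.3e-09, and adjusted p = 0.42 with an estimated correlation. Oas2 rose from 1.49 ± 0.00433 to 185 ± 6.04 CPM, Oasl2 from 1.27 ± 0.161 to 156 ± 10.5 CPM, and Gbp3, a guanylate-binding GTPase, from 1.22 ± 0.109 to 54 ± 0.851 CPM. Atf3 fell to 0.90 ± 0.185 CPM, Gjb2 to 0.309 ± 0.219 CPM, Egr3 to 1.7 ± 0.224 CPM and Nipal1 to 1.85 ± 0.0661 CPM. Hbegf, a heparin-binding ligand of the EGF receptor, fell from 85.3 ± 6.43 to 3.88 ± 0.559 CPM, and Spp1 from 1394 ± 8.04 to 84.6 ± 2.95 CPM. Slc16a3 fell from 106 ± 2.87 to 5.62 ± 1.06 CPM, Noct from 125 ± 7.32 to 8.09 ± 0.342 CPM and Fosb from 35 ± 4.29 to 1.82 ± 0.466 CPM. Smooth muscle and contractile genes counted 0 higher and 19 lower of 21 tested (the same adjusted over the list alone), with camera adjusted p = 1.0e-14, and adjusted p = 0.2 with an estimated correlation. Vcl fell from 1004 ± 7.29 to 114 ± 4.46 CPM. Of 28 tested AP-1 and immediate-early genes, 1 rose and 23 fell (2 and 23 adjusted over the list alone), with camera adjusted p = 1.9e-12, and adjusted p = 0.2 with an estimated correlation. Dusp5, a MAP kinase phosphatase, fell by 3.3 on the log2 scale. Among TGF-beta pathway genes, 3 of 22 tested rose and 15 fell (the same adjusted over the list alone), with camera adjusted p = 9.7e-07, and adjusted p = 0.39 with an estimated correlation. Glycolysis genes counted 3 higher and 16 lower of 22 tested (the same adjusted over the list alone), with camera adjusted p = 5.1e-09, and adjusted p = 0.39 with an estimated correlation. Of 21 tested hypoxia genes, 3 rose and 16 fell (the same adjusted over the list alone), with camera adjusted p = 2.0e-07, and adjusted p = 0.39 with an estimated correlation. Egln3, the oxygen-sensing hydroxylase of the hypoxia list, rose from 25.3 ± 0.109 to 67.1 ± 22.8 CPM.

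The factor genes were higher in D8 than in D2 by 1.3 (Pou5f1), 0.92 (Sox2), 0.84 (Klf4) and 0.86 (Myc) on the log2 scale (camera adjusted p = 0.017, and adjusted p = 0.42 with an estimated correlation). Among genes of the pluripotency network, 10 of 16 tested rose and 4 fell (the same adjusted over the list alone), with camera adjusted p = 0.21. L1td1 rose from 8.93 ± 0.219 to 113 ± 3.93 CPM and Tfcp2l1 from 0.351 ± 0.0643 to 8.02 ± 0.306 CPM. Epithelial genes counted 18 higher and 5 lower of 24 tested (the same adjusted over the list alone), with camera adjusted p = 0.035, and adjusted p = 0.39 with an estimated correlation. This call ended with a filter at 5 CPM (adjusted p = 0.13) and with voom (adjusted p = 0.065). Krt8 rose from 2.4 ± 0.336 to 125 ± 13 CPM, Dsg2 from 0.447 ± 0.069 to 23.1 ± 0.355 CPM and Cdh1 from 5.07 ± 0.899 to 36.5 ± 5.87 CPM, while Krt19 fell from 31.1 ± 0.367 to 4.14 ± 0.705 CPM. Of 20 tested genes of stratified epithelium, 12 rose and 2 fell (the same adjusted over the list alone), with camera adjusted p = 0.1. Lgals7 rose from 1.67 ± 0.04 to 123 ± 9.52 CPM and Evpl, the cornified envelope protein envoplakin, from 10.8 ± 0.144 to 64.6 ± 6.53 CPM. Among fibroblast and mesenchymal genes, 17 of 39 tested rose and 15 fell (the same adjusted over the list alone), with camera adjusted p = 0.66. Their median change was 0.03 and their mean 0.45, while camera pointed lower. Lum, Dcn, Pdgfra and Meox2, a mesenchymal homeobox gene, rose by 6.1, 3.12, 2.83 and 2.75 on the log2 scale. Thy1 fell by 0.46, and Col1a1 stood at 11430 ± 705 CPM against 10870 ± 26.5 CPM (adjusted p = 0.58). Genes of mitosis and G2/M counted 3 higher and 20 lower of 32 tested (the same adjusted over the list alone), with camera adjusted p = 2.0e-04, and adjusted p = 0.56 with an estimated correlation. Of 33 tested genes of DNA replication and S phase, 11 rose and 8 fell (11 and 7 adjusted over the list alone), with camera adjusted p = 0.47. Their median change was 0.07, while camera pointed lower.

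In total 7258 genes were higher and 3549 lower in D8 than in D2 (limma), and 1860 and 747 of these changed at least 2-fold. The median of all tested genes shifted by 0.167, and the share of called genes that were higher was 67.2% on the deposited scale, 51.4% after median-of-ratios scaling and 45.1% after quantile normalization.

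Genes called in the first step overlapped in part with those called in the last. Of the 725 genes higher in the last step, 376 had been higher in the first, against 296.3 expected (odds ratio 1.59, one-sided Fisher's exact p = 6.1e-10), among them Lum, Dcn, Dsg2 and Col17a1. Of the 674 genes lower in the last step, 194 had been lower in the first, against 146.1 expected (odds ratio 1.49, exact p = 5.7e-06), among them Lama1 and E2f8. Turns from higher to lower numbered 308 against 275.4 expected (odds ratio 1.23, exact p = 0.0052), among them Pde2a. Turns from lower to higher numbered 103 against 157.2 expected (odds ratio 0.59), fewer than expected. The one-sided test looks for an excess only, so this deficit was not tested. The excess of turns from higher to lower ended with a pseudocount of 0.1 (odds ratio 1.15, exact p = 0.059), a filter at 5 CPM (1.11), and without D4 replicate 2 (1.09), D6 replicate 2 (1.18) or D8 replicate 1 (1.01). The odds ratio of genes higher in both steps was 2.44 without D2 replicate 1, 3.11 without D6 replicate 1, 3.08 without D8 replicate 1 and 2.39 without D8 replicate 2. That of turns from lower to higher was 0.28 without D6 replicate 1 and 0.35 without D8 replicate 1. Without a filter on low values the odds ratios were 2.65 for genes higher in both, 3.69 for genes lower in both and 2.54 for turns from higher to lower. Both steps use the same estimate of each gene's spread, which can raise the overlap of calls in any direction. Fits of only the 2 days compared do not share it. They gave odds ratios of 2.25 for genes higher in both, 1.28 for genes lower in both, 1.49 for turns from higher to lower and 0.5 for turns from lower to higher. Genes are not independent replicates, and quantile normalization lowered the odds ratio of the genes lower in both steps to 1.01 (exact p = 0.48), below that of turns from higher to lower (1.47, exact p = 1.0e-06).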

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

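The voom fit was the only setting chosen after seeing the data, and where a result changed with a setting or a left-out library, the cause was not tested. Each named gene was counted once per contrast in which it was named. Of these pairs of gene and contrast, 674 kept their side of the threshold with voom, and their direction where called. The number was 660 with a pseudocount of 0.1, 658 with median-of-ratios scaling, 640 with quantile normalization and 554 without a filter on low values. Calls lost were 10, 24, 25, 40 and 130 in the same order, and the replicate block, which pairs libraries by number, lost 0 of them. With that block 797 genes were higher and 796 lower in D8 than in D6. The setting with an estimated correlation ended 67 list calls, each call that camera had made with the preset value. The size of the correlation does not account for all of them. The estimate lay below the preset 0.01 for BMP and ID genes in D6 against D4 (-0.005) and for adipocyte genes in D4 against D2 (-0.031). Their camera p-values before adjustment still rose, from 0.0012 to 0.024 and from 0.0092 to 0.054. The test fry, which does not compare a list with other genes, differed by step. In D8 against D6 its lowest adjusted p was 0.085 (epithelial), with 0.16 for mitosis and G2/M and 0.54 for interferon response. In D4 against D2 fry passed lists that camera did not, such as the pluripotency network (adjusted p = 3.3e-04) and epithelial genes (0.001). Depth limits genes near the floor of 3 reads. Nanog, which lay above that floor, and most of the pluripotency network were left out by the filter at 1 CPM.

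An added 2-fold threshold left 981 genes higher and 528 lower in D4 than in D2, 300 and 37 in D6 than in D4, 40 and 6 in D8 than in D6, and 1860 and 747 in D8 than in D2. With that threshold the odds ratio was 5.61 for genes higher in both steps (11 genes) and 5.62 for genes lower in both (1 gene, exact p = 0.19). It was 7.34 for turns from higher to lower (2 genes, exact p = 0.051) and 0 for turns from lower to higher (0 genes, 1.4 expected). The odds ratio of turns from higher to lower was 1.15 with a pseudocount of 0.1 and 1.11 with a filter at 5 CPM. Without a filter on low values 210 genes were higher and 134 lower in D8 than in D6. Quantile normalization gave 2942 genes lower in D6 than in D4, 4819 higher and 5876 lower in D8 than in D2, and an odds ratio of 1.01 for genes lower in both steps. It reversed the ribosomal protein list in D4 against D2 (0.02), mt-Nd1 in D6 against D4 (0.03), and Ascl2 (-0.05) and Fgfr2 (-0.02) in D8 against D2. Among the lists that passed with fry, fry took the opposite direction to camera for 6: in D4 against D2 primitive and visceral endoderm (0.05), endothelial (0.09) and Hox clusters (0.08), and in D8 against D2 fibroblast and mesenchymal (0.03), Hox clusters (0.2) and nuclear non-coding RNA (-0.01).

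Leaving out a library gave 212 to 907 genes higher and 186 to 836 lower in D8 than in D6. The counts moved most without D8 replicate 1 (212 and 186), D8 replicate 2 (238 and 305), D6 replicate 1 (288 and 249) and D6 replicate 2 (294 and 201). They also moved by more than 1.5 times without D2 replicate 1 (470 and 413) or D2 replicate 2 (465 and 407). The odds ratio of turns from higher to lower ranged from 1.01 without D8 replicate 1 to 1.71 without D8 replicate 2, and it was 1.09 without D4 replicate 2 and 1.18 without D6 replicate 2. The interferon list in D8 against D6 had a median of -0.49 without D6 replicate 1, -0.15 without D8 replicate 1 and 0.07 without D6 replicate 2.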

Other observations

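The 6 tests of technical explanations and the split of the Hox genes were chosen after the results were seen, and Ier2, Krt18, Tsix, Gapdh-ps15 and Gm47283 after their values were seen. Counts and levels of the gene groups compare D8 with D2 unless D4 is named. Among germline and meiosis genes, 8 of 9 tested rose and 0 fell (the same adjusted over the list alone), with camera adjusted p = 0.052. Piwil2 reached 38.2 ± 7.02 CPM from 0.472 ± 0.0338 CPM, and Tdrd1, a tudor protein of the piRNA pathway, rose from 0.646 ± 0.0722 to 5.47 ± 0.671 CPM. Hox genes counted 15 higher and 9 lower of 32 tested (the same adjusted over the list alone), with camera adjusted p = 0.93, while their median of 0.2 and mean of 0.26 lay above 0 and camera pointed lower. Of 21 tested Hox genes of the paralogue groups 1 to 8, 15 rose and 1 fell, among them Hoxc4 from 6.36 ± 1.04 to 17.9 ± 1.93 CPM and Hoxa5 from 10.6 ± 0.778 to 25.7 ± 0.78 CPM. Of 11 of the groups 9 to 13, 0 rose and 8 fell, among them Hoxb9 from 15.3 ± 1.08 to 9.34 ± 0.504 CPM. Of 24 tested imprinted genes, 13 rose and 8 fell (14 and 8 adjusted over the list alone), with camera adjusted p = 0.81. Cdkn1c, a cell cycle inhibitor, rose from 3.06 ± 0.0263 to 37.6 ± 11.4 CPM, Peg3, a zinc finger protein, from 52.5 ± 0.961 to 315 ± 14 CPM, and the non-coding RNA H19 from 1094 ± 0.792 to 3591 ± 163 CPM, while the transporter gene Slc38a4 fell from 95.2 ± 0.136 to 28.7 ± 0.466 CPM. Among telomere maintenance genes, 8 of 12 tested rose and 0 fell (the same adjusted over the list alone), with camera adjusted p = 0.21. Tert, the telomerase reverse transcriptase, rose from 3.58 ± 0.622 to 10.4 ± 0.727 CPM. SWI/SNF and chromatin remodeler genes counted 13 higher and 5 lower of 27 tested (the same adjusted over the list alone), with camera adjusted p = 0.93. Smarca2, the BRM helicase, rose from 63.7 ± 0.22 to 223 ± 13.1 CPM, and Hmga2, an architectural chromatin protein, fell from 292 ± 4.59 to 75.5 ± 0.192 CPM. Of 12 tested genes of the replication-dependent histone list, 1 rose and 11 fell in D4 against D2 (the same adjusted over the list alone). Camera gave an adjusted p of 1.6e-04, and 0.36 with an estimated correlation. The list includes H1f0, a linker histone gene that is expressed independently of replication. With a filter at 5 CPM the adjusted p of the histone list was 0.19. Among mitochondrially encoded genes, 12 of 13 tested rose and 0 fell (the same adjusted over the list alone), with camera adjusted p = 0.07. The complex I gene mt-Nd2 rose from 2961 ± 1.33 to 5731 ± 399 CPM. Nuclear genes of oxidative phosphorylation counted 1 higher and 10 lower of 34 tested (1 and 7 adjusted over the list alone), with camera adjusted p = 0.0062, and adjusted p = 0.63 with an estimated correlation, in D4 against D2. Without D4 replicate 2 the adjusted p of that list was 0.14, and 8 of its genes were higher and 0 lower in D6 against D4, and 9 higher and 7 lower in D8 against D2 (camera adjusted p = 0.4). Of 10 tested nuclear non-coding RNAs, 3 rose and 2 fell (the same adjusted over the list alone), with camera adjusted p = 0.76. Their median was -0.01 and their mean 0.16, and Neat1, the RNA of paraspeckles, fell from 733 ± 4.18 to 412 ± 17.5 CPM.

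Lineage lists moved in part between D2 and D8. Among neural genes, 6 of 10 tested rose and 3 fell (7 and 3 adjusted over the list alone), with camera adjusted p = 0.82, and camera pointed lower, against a median of 0.38. Sox1 rose to 6.41 ± 2.72 CPM and Mapt, the tau protein, from 1.02 ± 0.319 to 8.09 ± 0.661 CPM, while Nes, the intermediate filament nestin, fell from 219 ± 1.51 to 49.4 ± 0.259 CPM. Trophoblast genes counted 4 higher and 0 lower of 6 tested (the same adjusted over the list alone), with camera adjusted p = 0.47. Gata2, a zinc finger factor, rose from 11.9 ± 0.246 to 35.1 ± 0.0923 CPM. Of 9 tested genes of primitive and visceral endoderm, 2 rose and 7 fell (the same adjusted over the list alone), with camera adjusted p = 0.035, and adjusted p = 0.42 with an estimated correlation. That call ended without a filter (adjusted p = 0.052), with one at 5 CPM (0.063), with median-of-ratios scaling (0.058) and with quantile normalization (0.24). Among genes of mesoderm and the primitive streak, 4 of 5 tested rose and 1 fell (the same adjusted over the list alone), with camera adjusted p = 0.66. Cartilage and bone genes counted 4 higher and 4 lower of 11 tested (the same adjusted over the list alone), with camera adjusted p = 0.38. Bglap, osteocalcin, rose from 1.3 ± 0.162 to 13.9 ± 1.45 CPM, and Col10a1, a collagen of hypertrophic cartilage, fell from 38.4 ± 1.42 to 8.11 ± 1.25 CPM. Of 10 tested endothelial genes, 6 rose and 4 fell (the same adjusted over the list alone), with camera adjusted p = 0.88. Eng, endoglin, rose from 53.9 ± 1.39 to 200.4 ± 7.08 CPM, and the receptor gene Flt1 fell from 69 ± 0.186 to 17.8 ± 2.64 CPM. Among skeletal muscle genes, 0 of 4 tested rose and 3 fell (the same adjusted over the list alone), with camera adjusted p = 0.028, and adjusted p = 0.32 with an estimated correlation, in D4 against D2. That call ended without a filter (adjusted p = 0.53) and with median-of-ratios scaling (adjusted p = 0.054). Adipocyte genes counted 0 higher and 6 lower of 9 tested (the same adjusted over the list alone), with camera adjusted p = 0.021, and adjusted p = 0.32 with an estimated correlation, in D4 against D2. Without a filter the adjusted p of the adipocyte list was 0.059, and 4 of its genes were higher and 0 lower in D6 against D4, and 3 higher and 3 lower in D8 against D2 (camera adjusted p = 0.38). Of 25 tested p53 targets and genes of cell cycle arrest, 11 rose and 11 fell (11 and 12 adjusted over the list alone), with camera adjusted p = 0.51, in D4 against D2, and camera pointed lower, with a median of -0.14 and a mean of 0.04. Pmaip1, the apoptosis gene Noxa, fell from 63.4 ± 3.59 to 17.6 ± 0.321 CPM, and Sesn1, a sestrin, rose from 10.9 ± 1.19 to 26.9 ± 0.135 CPM. Among apoptosis regulators, 10 of 20 tested rose and 4 fell (the same adjusted over the list alone), with camera adjusted p = 0.82. Wnt pathway genes counted 15 higher and 8 lower of 27 tested (15 and 9 adjusted over the list alone), with camera adjusted p = 0.84. The secreted Wnt antagonist gene Sfrp1 rose from 25.6 ± 0.839 to 156 ± 25.7 CPM. Of 26 tested lysosome and autophagy genes, 6 rose and 11 fell (the same adjusted over the list alone), with camera adjusted p = 0.018, and adjusted p = 0.41 with an estimated correlation, in D4 against D2. Quantile normalization gave the lysosome list an adjusted p of 0.23. Among surface markers of pluripotent cells and their glycosylation enzymes, 7 of 13 tested rose and 6 fell (the same adjusted over the list alone), with camera adjusted p = 0.4, and camera pointed lower, against a median of 0.26. Of the erythroid list 2 of 15 genes passed the filter, with a highest value of 56.18 CPM, of Hbb-y, an embryonic globin that stood at 21.3 ± 1.63 CPM in D2 and 51.9 ± 1.86 CPM in D8. Of the list of genes of 2-cell embryos 0 of 15 passed, with a highest value of 1.05 CPM. Krt18, the usual partner of Krt8, stayed between 0 and 0.52 CPM in all libraries.

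Xist was high and the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty near 0, although the labels name male embryos, and 2 of 281 Y-chromosome genes, Gapdh-ps15 and Gm47283, reached 1 CPM. If all cells were XY and their Y-linked reads had been lost in the counting, Xist would stay near 0, and its lowest level was 702 CPM. This does not cover a mix of XX and XY cells. Reads of the antisense gene Tsix counted as Xist are argued against by the lowest ratio of Xist to Tsix, 70.3. A label that names the wrong sex stays open as a candidate explanation. No biological explanation was tested.

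Fos, Fosb, Egr1, Ier2, Zfp36 and Dusp1 were highest in D4. Heat stress at the D4 harvest did not show in the heat shock genes, of which 0 of 15 had both D4 libraries above every D2 and D6 library. That outcome was nearly fixed beforehand, because 14 of them were called lower in D4 than in D2. Dissociation stress at the harvest was not tested by this list and stays open. The 6 genes were chosen as highest in D4, but a single deviating D4 library is argued against, because the lower D4 library stood at no less than 2.08 times the highest library of the other days for each of them, and the D4 libraries lay close together (Fos at 129.8 ± 1.54 CPM, Egr1 at 396 ± 3.08 CPM, Dusp1 at 81.6 ± 0.262 CPM). The time between the daily change of medium and the harvest is not given and may have differed between days. No biological explanation was tested.

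Interferon response genes were higher from D4 on. A gain of macrophages or other blood cells between D2 and D4 is argued against by the 21 macrophage and haematopoietic genes. Their median change was 0.12 (upper quartile 0.25), against a lower quartile of 2.01 for the interferon genes. Of the 21, 0 are in another list, and 4 were called higher and 1 lower, with Mrc1 among the higher. The most abundant of the 21, Lyz2 and Laptm5, stood at 43.2 and 17.2 CPM in D2 and at 50.7 and 18.6 CPM in D4. As 19 of the 21 were at 1 CPM or more in both D2 libraries, such cells present on both days are not covered by this comparison. Library scaling or composition is argued against by a median change of the interferon list of at least 2.83 under median-of-ratios scaling and quantile normalization. No biological explanation was tested.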
